A study of Mus musculus with 8 samples.

How the data were processed

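Liver RNA of female NFS/sld mice was hybridised to 8 one-colour Agilent arrays, 4 from mice thymectomised on day 3 after birth (Tx), 8 weeks after surgery, and 4 from mice without thymectomy (nonTx), per the labels. Per the labels' protocols, 0.5 ug of RNA was labelled for each array. The scanner files hold the intensity of each spot, background-subtracted and spatially detrended with Feature Extraction 10.7.1.1 per the file headers; the submitters' processing notes name version 9.1, and the headers were followed. The deposited table holds the same intensities and log2 values that the authors scaled to the 75th percentile and centred on each probe's median over the 8 arrays, which was found by rebuilding them within 0.0016. Its log2 difference column, made by the authors, is the mean of Tx minus the mean of nonTx. The medians of the deposited log2 columns were 0.03, -0.05, -0.06 and -0.07 for nonTx replicates 1 to 4 and -0.12, 0.09, 0.05 and 0.15 for Tx replicates 1 to 4.

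Each array had 62976 spots, 59305 of them for genes, which gave 56605 probes after spots of the same probe were averaged (300 probes had several spots). Control spots were left out and spots marked as non-uniform or as population outliers were set to missing, between 54 and 120 per array; 0 spots were saturated. The log2 intensity minus the array's 75th percentile was used. A probe was tested where it was well above background on at least 3 of 4 arrays of a group and had at least 2 values per group, which left 30955 probes with 46 missing values. Gene symbols came from the files, updated through Entrez IDs: of 46119 probes with a symbol or ID, 43901 matched and 1276 symbols were updated. A gene was represented by its brightest tested probe, 16495 genes in all. Where a probe was not well above background on any array of a group, the fold is a bound: the brighter group's mean against the dimmer group's mean of, per array, the higher of the lowest signal well above background and the probe's own. No coordinates are given, since the headers name a genome build other than that of the reference at hand.

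Depth was the signal over background. The 75th percentile of the signal was 301.8, 276, 289 and 273.6 in nonTx replicates 1 to 4 and 330, 249.6, 229.8 and 224.8 in Tx replicates 1 to 4. The number of arrays, 4 per group, limits the precision. All of the 10 spike-in RNAs added to each sample were higher in Tx after this scaling, by 0.06 to 0.37 on the log2 scale. Of these, 2 had mean signals of only 3.62 and 4.81, near the floor, so their differences say little. The standard deviations of the spike-in RNAs between Tx arrays ran from 0.21 to 0.59. The spike-in differences are as large as the medians of several gene lists called higher below, so the direction of such small shifts depends on the scaling.

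Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with a variance trend, 6 residual degrees of freedom), with Benjamini-Hochberg adjustment and a threshold of 0.05; errors are standard errors from this fit. Files were read with the R package data.table, version 1.17.8. Lists of genes, 40 with 987 genes in total, were tested with limma's camera (preset correlation 0.01, two-sided, adjusted over the 40 lists), with at least 5 measured members per list. The lists covered T cells, B cells, plasma cells, NK cells, Kupffer cells, neutrophils, MHC class II, type I interferon, interferon gamma, acute phase, cytokines, complement, stellate cells, cholangiocytes, sinusoidal endothelium, hepatocyte proteins, bile acids, cholesterol, fatty acids, PPARa, gluconeogenesis, glucocorticoids, xenobiotic metabolism, Nrf2, female-biased and male-biased genes, clock, immediate-early genes, heat shock, unfolded protein response, cell cycle, oxidative phosphorylation, ribosomal proteins, pericentral and periportal hepatocytes, erythroid cells, exocrine pancreas, adipocytes, muscle and autoantigens. The design, the lists, the rule for naming genes and the alternative settings, except where stated, were chosen before the data were examined. By that rule, the genes named were those past the threshold with the largest differences, and where under 5 passed in a direction, the 5 with the smallest p; and per list up to 3 past the threshold, filled up to 2 by the smallest p. Other members named beside them, the lists of immunoglobulin and T cell receptor chains (taken from probe descriptions and adjusted with the 40 lists over 43 lists), and the genes high in single arrays were chosen after their values were seen.

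The alternatives were normexp background correction (offset 50, on the median signal, chosen after the files were seen to hold no mean signal), quantile normalization, scaling to the median or to bright probes, the authors' log2 values, no filter or a stricter filter on dim probes, a floor, outlier spots kept, no variance trend, robust variance, array weights, a replicate block, the mean of a gene's probes, each array left out in turn, other thresholds, a plain equal-variance test, camera with an estimated correlation, and fry. The steps were tested on simulated data for Tx against nonTx. On 30928 simulated probes with 200 changed, 64 of 100 probes changed 2-fold and 93 of 100 changed 4-fold were called, with 7 unchanged probes called. A shift of -0.5 given to the 20 T cell genes among 16486 simulated genes was called at an adjusted p of 2.07e-20, with 0 of the 39 other lists called. The simulated genes varied independently of one another, whereas the estimated correlation within the real lists reached 0.765 (interferon gamma). The simulation therefore cannot show how often lists of correlated genes are called by chance.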

Results

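Gene expression was measured in the liver of female NFS/sld mice, a strain in which removal of the thymus soon after birth is used to model primary Sjögren's syndrome, an autoimmune disease of the salivary and lacrimal glands. One group of 4 arrays held liver RNA from mice whose thymus was removed on day 3 after birth (Tx), taken 8 weeks after the operation, and the other group of 4 held liver RNA from mice with their thymus in place (nonTx). The comparison asks which liver transcripts differ once the thymus, the organ in which T cells mature, has been taken out. The annotation used here gives the time after surgery for Tx alone. It does not state the age of the nonTx mice or whether they had a sham operation. The labels call the replicates independent without saying that each came from its own animal, so p-values measure the spread between these samples. Between 51.1% and 57.12% of the probes of an array were well above background, and the correlation between any pair of arrays lay between 0.977 and 0.994. For these arrays the number of replicates, 4 per group, limits the precision.

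The liver arrays of the Tx group held lower levels of T cell transcripts than those of the nonTx group. Of the 20 measured genes of the T cell list, 17 were lower in Tx, with a median log2 difference of -0.47 (n = 4 arrays per group), and 8 fell when adjusted over the list alone. Among these were Cd3d and Cd3g, which encode subunits of the CD3 complex of the T cell receptor, and the kinase gene Lck. They also included the costimulatory receptor Cd28, the surface receptor Cd5, and Lef1 and Ccr7, a transcription factor and a homing receptor of naive T cells. Cd3d was 2.25-fold lower (log2 difference -1.17 ± 0.14, SE) and Cd3g 1.79-fold lower (-0.84 ± 0.17), each lower on all 4 Tx arrays than on any nonTx array. Lef1 differed by -1.30 ± 0.37 and was well above background on only 1 of the 4 Tx arrays. Not every T cell gene lay lower: Cd3e, another CD3 subunit, differed by 0.13 ± 0.12, Cd4 by 0.32 ± 0.18 and Cd247 by 0.34 ± 0.26. By camera with its preset correlation, the T cell list fell at an adjusted p of 4.39e-08. The adjusted p was 0.607 with an estimated correlation and 0.0666 with fry, and over all alternatives it lay between 6.55e-11 and 0.607. Of the 35 ways to split the arrays 4 against 4, the real one included, 2 gave a camera p as small for T cells. The size of the shift depended on the processing, with a list median of -0.20 with normexp, which changed the signal used, the background correction and the offset together. Cd3d was among 5 probes that shared the smallest adjusted p over all probes, 0.0577, and did not pass alone.

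The chains of the T cell receptor itself, listed after the data were seen because their probes carry a description but no gene symbol, lay lower too. Of 21 measured chains, 14 were lower in Tx, 7 of them when adjusted over the list alone, and the median log2 difference was -0.27. The constant region 2 of the beta chain was lower by -0.95 ± 0.17 on the log2 scale on its brightest probe. The constant regions of the gamma chain, which marks gamma-delta T cells, differed by -1.51 ± 0.34 for region 1 and -1.32 ± 0.25 for region 3. Variable segments of the alpha chain went both ways, with log2 differences from -0.46 to 0.38. The list of receptor chains fell by camera at an adjusted p of 0.000204 over 43 lists (adjusted p = 0.422 with an estimated correlation). It lost its call with normexp background correction (adjusted p = 0.0621) and changed direction with no filter on dim probes (adjusted p = 0.942). Its adjusted p lay between 7.39e-06 and 0.942 over the alternatives.

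Immunoglobulin constant-region transcripts were higher in the Tx livers. Of 10 measured constant regions, a list also made after the data were seen, 9 were higher and 7 rose when adjusted over the list alone, with a median log2 difference of 0.95. The constant region of the alpha heavy chain, the IgA class, was 2.09-fold higher (1.06 ± 0.12, SE, n = 4 arrays per group). The kappa light chain constant region was 2.11-fold higher (1.08 ± 0.13) and the gamma 2C heavy chain constant region, an IgG class, 4.06-fold higher (2.02 ± 0.39). The gamma 2B heavy chain constant region differed by 2.11 ± 0.45, whereas the delta heavy chain constant region, found on naive B cells, differed by -0.10 ± 0.26. Tx replicate 2 weighed heavily in the IgG classes: without it the gamma 2C region was 2.95-fold and the gamma 2B region 2.99-fold higher, while the gamma 3 region went from 1.58-fold to 0.968-fold. The alpha and kappa regions were 2.04-fold and 1.97-fold higher without it, and the mu heavy chain region went from 1.79-fold to 1.38-fold. The mu region, among the 7, differed by 0.84 ± 0.32 on its brightest probe but by 0.165 and 0.229 on its other tested probes. The gamma 1 region, also among the 7, was well above background on only 1 of 4 nonTx arrays. The median deviation of the constant regions stood at 0.54, 1.19, 0.09 and 0.44 in Tx replicates 1 to 4 and between -0.59 and -0.28 in nonTx. Jchain, which joins IgA and IgM into polymers, was 2.57-fold higher (1.36 ± 0.22, adjusted p = 0.102). The alpha and kappa constant regions each reached an adjusted p of 0.0577 over all probes. Camera called the constant regions higher at an adjusted p of 2.59e-06 over 43 lists (adjusted p = 0.422 with an estimated correlation), with a range over the alternatives from 2.31e-08 to 0.422. The constant regions were set apart from the other chains after the values were seen, so their call partly restates that choice. The 38 measured variable segments had a median of 0.09, with 21 higher. As a list of their own, these segments were left out of the adjustment. All 48 chains together had a median of 0.39 (adjusted p = 0.000865, and adjusted p = 0.757 with an estimated correlation). That call ended without Tx replicate 2 (adjusted p = 0.0586, range over the alternatives 2.31e-08 to 0.757). The plasma cell list fixed beforehand was not called, with a median of 0.13 (adjusted p = 0.428). Its 9 measured genes are markers of antibody-secreting cells and include 0 of these constant regions. Its members included Jchain and Mzb1, an antibody assembly factor, at 0.53 ± 0.20.

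**Figure D1:**
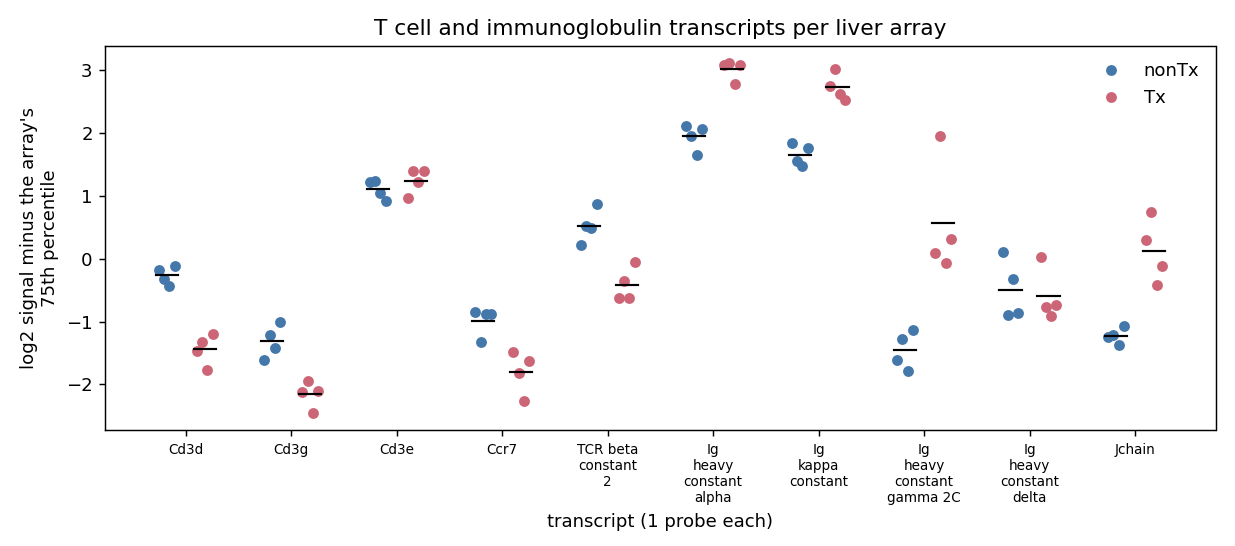
Each dot is 1 liver array, for 1 probe per transcript, with the log2 signal minus the array's 75th percentile on the vertical axis and black bars at the mean of each group's 4 arrays. Cd3d lies between -0.44 and -0.12 in nonTx and between -1.77 and -1.19 in Tx, and the alpha heavy chain constant region between 1.65 and 2.12 in nonTx and between 2.78 and 3.11 in Tx, while Cd3e and the delta constant region overlap between the groups.

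B cell genes did not move with the immunoglobulins. The 16 measured B cell genes had a median log2 difference of 0.05, with 10 higher and 6 lower (adjusted p = 0.987). Cd79b differed by 0.33 ± 0.18. Blnk, an adaptor of B cell receptor signalling, differed by 0.59 ± 0.24 and the complement receptor Cr2 by -0.45 ± 0.15. Markers of Kupffer cells, the resident macrophages of the liver, had a median of 0.02 over 26 genes (adjusted p = 0.97), and neutrophil and monocyte genes a median of 0.09 over 18 (adjusted p = 0.423). Single genes of these lists differed more, among them the integrin Itgam at -1.52 ± 0.53 and the neutrophil gene Retnlg at 0.90 ± 0.20, without passing the test.

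Natural killer and cytotoxic lymphocyte genes were lower in Tx, with 11 of 16 measured genes lower, 1 of them when adjusted over the list alone, and a median log2 difference of -0.32. Txk, a kinase of T and NK cells, differed by -0.95 ± 0.24 and Il2rb, a subunit of the interleukin 2 and 15 receptors, by -0.85 ± 0.25. The death ligand Fasl was at least 1.47-fold lower and Ifng, the interferon gamma gene, at least 1.37-fold lower, since neither was well above background on any Tx array. Both genes entered the test only through their nonTx signal, so their lower direction partly restates the filter. The granule genes Gzma, Gzmb and Prf1 differed by 0.06 ± 0.34, 0.07 ± 0.41 and 0.03 ± 0.20. Camera called the list lower at an adjusted p of 0.000646, and the value was an adjusted p = 0.852 with an estimated correlation; without any 1 array it lay between 7.65e-06 and 0.0266.

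Genes of antigen presentation and of the interferon gamma response were called lower too, with a wide spread between arrays of the same group. The 14 measured genes of MHC class II and dendritic cells had a median log2 difference of -0.40 with 12 lower (adjusted p = 0.018, and adjusted p = 0.852 with an estimated correlation). Ciita, the master regulator of MHC class II, differed by -0.89 ± 0.48. Of 27 interferon gamma response genes 22 were lower, with a median of -0.33 (adjusted p = 0.0228, and adjusted p = 0.902 with an estimated correlation). By limma 0 of them passed when adjusted over the list alone, and 0 had an unadjusted p under 0.05. Taken as the median deviation of its genes from their mean over the 8 arrays, the interferon gamma list stood at -0.46, 0.24, 0.15 and 0.71 in nonTx replicates 1 to 4 and at -0.61, 0.92, -0.38 and -0.41 in Tx replicates 1 to 4. Its call ended without nonTx replicate 2 (adjusted p = 0.0669) or 4 (0.523) and without Tx replicate 1 (0.302), 3 (0.066) or 4 (0.209). That of the MHC class II list ended without nonTx replicate 4 (0.159) and without Tx replicate 1 (0.0703) or 4 (0.14). The 31 genes of the type I interferon response had a median of 0.01 (adjusted p = 0.618), and were called lower without nonTx replicate 1 (0.0302) or Tx replicate 2 (0.0225). The interferon gamma call also ended with scaling to bright probes (0.0776) and array weights (0.0712), and the MHC class II call with no filter on dim probes (0.15). Over the alternatives the adjusted p ran from 1.51e-06 to 0.902 for the interferon gamma list, from 0.000107 to 0.852 for MHC class II and from 0.0225 to 0.992 for type I interferon.

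**Figure D2:**
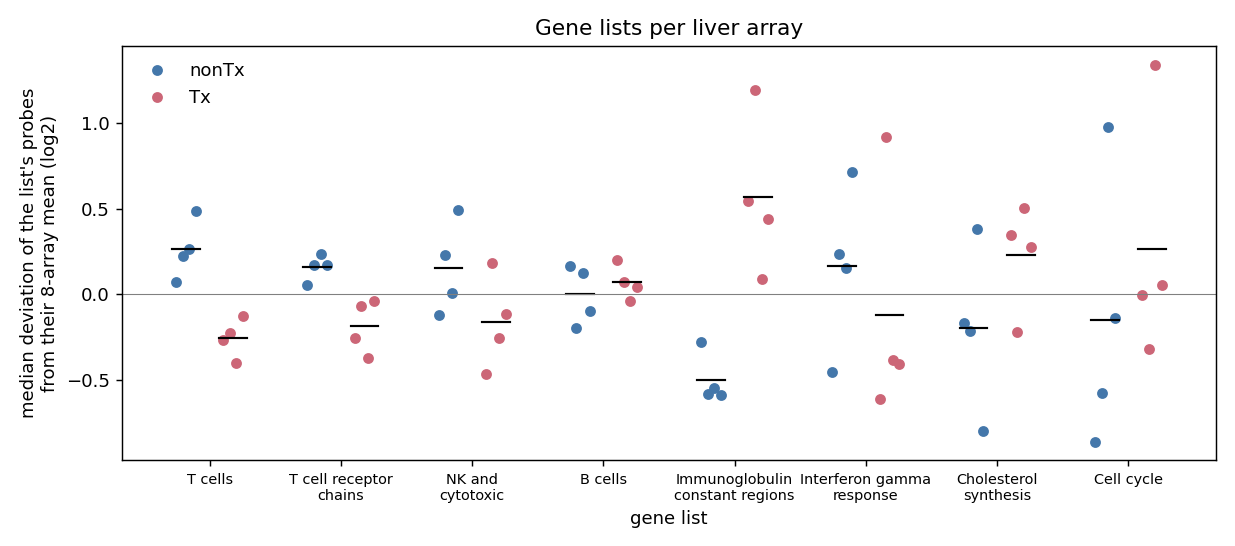
Each dot is 1 liver array, with the median deviation of a gene list's probes from their mean over the 8 arrays on the vertical axis (log2) and black bars at the mean of each group's 4 arrays. The T cell list lies between 0.07 and 0.49 in nonTx and between -0.41 and -0.13 in Tx, whereas the interferon gamma response, cholesterol synthesis and cell cycle lists overlap between the groups.

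Hepatocyte genes of lipid synthesis and detoxification were called modestly higher in Tx. These rises are relative to the scaling. After it every spike-in RNA was higher in Tx too, by 0.06 to 0.37 on the log2 scale, though 2 were near the floor. Of the 35 ways to split the arrays 4 against 4, the real one included, 13, 15 and 6 gave a camera p as small for cholesterol, fatty acid and xenobiotic genes. All 24 measured cholesterol synthesis genes were higher, with a median log2 difference of 0.46 (adjusted p = 0.000173, and adjusted p = 0.852 with an estimated correlation). Tm7sf2 and Ebp, both enzymes of the late steps of the pathway, differed by 0.64 ± 0.21 and 0.30 ± 0.11. On single arrays this list stood at -0.17, -0.21, 0.38 and -0.80 in nonTx replicates 1 to 4 and at 0.34, -0.22, 0.50 and 0.28 in Tx replicates 1 to 4. Fatty acid and triglyceride synthesis genes had a median of 0.24 with 22 of 27 higher, including Acss2 at 0.66 ± 0.23 and the acetyl-CoA carboxylase gene Acacb at 0.52 ± 0.20 (adjusted p = 0.0213, and adjusted p = 0.885 with an estimated correlation). That call ended without nonTx replicate 1 (adjusted p = 0.161) and without Tx replicate 1 (0.123) or 3 (0.204). It also ended with normexp (0.0596), quantile normalization (0.147), median scaling (0.119), no filter on dim probes (0.154) and array weights (0.105). Xenobiotic metabolism genes had a median of 0.20 with 37 of 40 higher, among them the cytochromes P450 Cyp2c54 at 0.40 ± 0.10 and Cyp2c40 at 0.49 ± 0.16 (adjusted p = 0.000646, and adjusted p = 0.852 with an estimated correlation). Over the alternatives the adjusted p ran from 2.37e-09 to 0.852 for cholesterol synthesis, from 0.000685 to 0.885 for fatty acid and triglyceride synthesis and from 2.48e-05 to 0.852 for xenobiotic metabolism, whose call ended with quantile normalization (0.0937).

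Genes expressed around the central vein and genes that are higher in male liver were also called higher in these female mice. Pericentral hepatocyte genes had a median log2 difference of 0.27, with 17 of 20 higher and 6 when adjusted over the list alone (adjusted p = 0.00099, and adjusted p = 0.646 with an estimated correlation). The glutamate transporter gene Slc1a2 differed by 0.54 ± 0.11 and Lhpp by 0.56 ± 0.13. Male-biased genes had a median of 0.31 with 23 of 26 higher, 2 of them when adjusted over the list alone, including Susd4 at 0.76 ± 0.16 (adjusted p = 0.000474, and adjusted p = 0.852 with an estimated correlation). Female-biased genes shared the direction, with 22 of 25 higher, a median of 0.19 and an adjusted p of 0.0615, and were called without nonTx replicate 1 (adjusted p = 0.0275) or 2 (0.0495) and without Tx replicate 3 (0.0282), and also with scaling to bright probes (0.0293) and the mean of a gene's probes (0.0265). Periportal genes had a median of 0.16 with 19 of 20 higher, among them Cyp2f2 at 0.42 ± 0.15 (adjusted p = 0.0493, and adjusted p = 0.885 with an estimated correlation). The periportal call ended without nonTx replicate 1 (0.309) or 3 (0.202) and without Tx replicate 1 (0.0913), 3 (0.0827) or 4 (0.161). It was kept in only 9 of 24 alternatives and also ended with normexp (0.21), quantile normalization (0.647), median scaling (0.0963), no filter (0.285) or a stricter filter on dim probes (0.0901), a floor (0.0589), array weights (0.0919) and the mean of a gene's probes (0.339). Over the alternatives the adjusted p ran from 0.000262 to 0.646 for pericentral, from 0.00291 to 0.885 for periportal, from 3.77e-06 to 0.852 for male-biased and from 0.0265 to 0.852 for female-biased genes.

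Brightly expressed housekeeping groups were called slightly higher. Ribosomal protein genes had a median log2 difference of 0.17 with 39 of 40 higher, among them Rpl15 at 0.30 ± 0.10 and Rpl10a at 0.23 ± 0.08 (adjusted p = 1.97e-06, and adjusted p = 0.852 with an estimated correlation). All 35 measured genes of oxidative phosphorylation were higher, with a median of 0.14, among them Cycs, cytochrome c, at 0.26 ± 0.09 (adjusted p = 7.74e-05, and adjusted p = 0.852 with an estimated correlation). With quantile normalization the ribosomal median was 0.01 with no call (adjusted p = 0.73), and that of oxidative phosphorylation was -0.01, the other direction (adjusted p = 0.893). Random gene lists matched on signal level had a middle median of 0.14 for the ribosomal and 0.15 for the oxidative phosphorylation list. The medians of the heat shock, complement, adipocyte and periportal lists also lay within the middle 95% of their matched lists, which ran from 0.02 to 0.18, from 0.07 to 0.18, from -0.16 to 0.19 and from 0.07 to 0.19. The median of all tested probes was 0.02, and 0.12 when arrays were scaled to their median, so these small shifts are relative to the scaling. Heat shock genes had a median of 0.17 with 16 of 18 higher, including the cochaperone Dnajb1 at 0.45 ± 0.13 (adjusted p = 0.0214, and adjusted p = 0.852 with an estimated correlation). That call ended without nonTx replicate 1 (0.223) or Tx replicate 2 (0.0933), and with normexp (0.127), quantile normalization (0.325), no filter on dim probes (0.154) and array weights (0.0611). Complement genes had a median of 0.14 with 16 of 21 higher, including C8b at 0.68 ± 0.19 (adjusted p = 0.0473, and adjusted p = 0.852 with an estimated correlation). That call ended without nonTx replicate 1 (0.0545) or 3 (0.206) and without Tx replicate 1 (0.107), 2 (0.105) or 4 (0.155). It also ended with normexp (0.504), quantile normalization (0.73), no filter (0.285) or a stricter filter on dim probes (0.0901), a floor (0.0587) and the mean of a gene's probes (0.263). All 7 measured adipocyte genes were higher, with a median of 0.17 and the fatty acid carrier Fabp4 at 0.47 ± 0.11 (adjusted p = 0.0365, and adjusted p = 0.646 with an estimated correlation). That call ended without nonTx replicate 2 (0.0639) and without Tx replicate 1 (0.0973), 2 (0.0584) or 4 (0.0707). It also ended with normexp (0.0598), median scaling (0.0838), no filter (0.549) or a stricter filter on dim probes (0.164) and array weights (0.0594). Over the alternatives the adjusted p ran from 1.3e-07 to 0.852 for ribosomal proteins, from 6.17e-07 to 0.893 for oxidative phosphorylation, from 0.00218 to 0.852 for heat shock, from 0.00635 to 0.852 for complement and from 0.00943 to 0.646 for adipocytes.

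**Figure D3:**
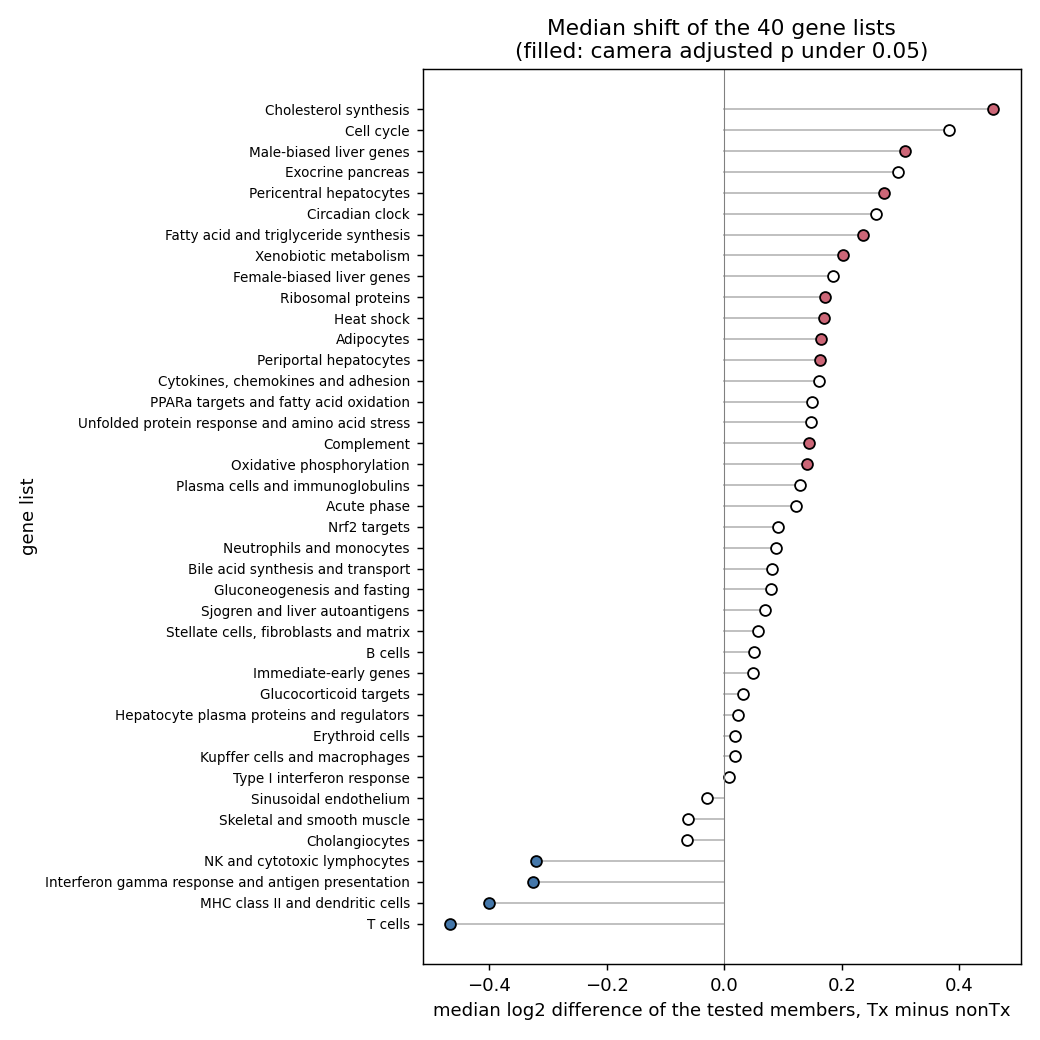
Each circle is the median log2 difference, Tx minus nonTx, over the measured members of 1 of the 40 gene lists, and filled circles mark the 15 lists called at an adjusted p under 0.05 by camera with its preset correlation, 11 higher and 4 lower. The T cell list lies lowest at -0.47 and cholesterol synthesis highest at 0.46, and 0 of the 15 calls held with an estimated correlation.

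The remaining liver groups were not called. Bile acid synthesis and transport genes had a median log2 difference of 0.08 (adjusted p = 0.854), with Cyp27a1, an enzyme of the acidic bile acid pathway, at 0.59 ± 0.17. PPARa targets had a median of 0.15 (adjusted p = 0.0624) and were called higher without nonTx replicate 1 (adjusted p = 0.000295) or 3 (0.00216) or Tx replicate 2 (0.0263), with scaling to bright probes (0.0377) and with the mean of a gene's probes (0.0265). Gluconeogenesis genes had a median of 0.08 (adjusted p = 0.97), although G6pc, which encodes glucose-6-phosphatase, differed by -0.62 ± 0.14. Plasma proteins of hepatocytes had a median of 0.02 (adjusted p = 0.97), with the transthyretin gene Ttr at -0.37 ± 0.07 on its brightest probe and the other direction on its other probe. Glucocorticoid targets had a median of 0.03 (adjusted p = 0.97) and Nrf2 targets of 0.09 (adjusted p = 0.0935, called without Tx replicate 1 at 0.0254 and with the mean of a gene's probes at 0.0269). Acute phase genes had a median of 0.12 (adjusted p = 0.0935) and were called higher without nonTx replicate 1 (0.00972) or 4 (0.048) or Tx replicate 3 (0.023), with array weights (0.0287) and with the mean of a gene's probes (0.045). Unfolded protein response genes had a median of 0.15 (adjusted p = 0.428) and clock genes of 0.26 (adjusted p = 0.431).

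Markers of scarring, bile ducts, vessels and other tissues were not called either. Stellate cell and matrix genes had a median log2 difference of 0.06 over 30 genes (adjusted p = 0.877), with Thy1, a surface protein of fibroblasts and T cells, at -0.85 ± 0.16 and the protease inhibitor Timp1 at 0.38 ± 0.10. Cholangiocyte genes had a median of -0.06 (adjusted p = 0.908), sinusoidal endothelial genes of -0.03 (adjusted p = 0.636), erythroid genes of 0.02 (adjusted p = 0.97) and skeletal and smooth muscle genes of -0.06 (adjusted p = 0.555). Exocrine pancreas genes had a median of 0.30 over 7 genes (adjusted p = 0.636, called higher without nonTx replicate 3 at 0.0349). Genes of autoantigens of Sjögren's syndrome and liver autoimmunity had a median of 0.07 (adjusted p = 0.915), with Nup62 at 0.29 ± 0.12 and Sp100 at 0.26 ± 0.11. Cytokine and chemokine genes had a median of 0.16 (adjusted p = 0.423, called higher without nonTx replicate 4 at 0.048), with Il1b at -1.01 ± 0.20 on its brightest probe and Tnf at 0.62 ± 0.14. Cell cycle genes had a median of 0.38 (adjusted p = 0.0685) and were called higher without nonTx replicate 3 (3.58e-05) or Tx replicate 2 (0.0111) or 4 (0.0246). They were also called with quantile normalization (0.0123), scaling to bright probes (0.0138) and the mean of a gene's probes (0.0265). Immediate-early genes had a median of 0.05, against the lower direction of their test (adjusted p = 0.128), and were called lower without Tx replicate 1 (0.00345), with normexp (0.0332), median scaling (0.038) and array weights (0.0292). Gadd45g, a stress-induced gene, was 4.18-fold lower (-2.06 ± 0.29) and Rgs1 differed by -1.14 ± 0.24. In 8 of the 40 lists the median and the test had opposite signs, and in 5 the median and the mean did.

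Among single genes, 0 of 30955 probes were higher and 0 lower in Tx at an adjusted p under 0.05 by limma, and the smallest adjusted p was 0.0577. A plain equal-variance test on the same values also called 0 in either direction. At an unadjusted p under 0.05 there were 4085 probes (13.2%), 2219 higher and 1866 lower, and for 2436 probes (7.87%) the values of the groups did not overlap, against 2.86% by chance. The named genes higher in Tx with the smallest p were Vav2 at 1.2 ± 0.17, Cyb561 at 0.99 ± 0.14 and the immunoglobulin heavy chain segment Igh-VJ558 at 0.94 ± 0.13. Raver1 followed at 1.2 ± 0.18, and Stat5a, a transcription factor downstream of growth hormone and cytokine receptors, stood at 1.36 ± 0.20 on 1 of its 2 probes. These 5 genes each had an adjusted p of 0.0851. Arrdc3 at 2.04 ± 0.23 and Cox7c at 0.78 ± 0.09, named after their values were seen, shared the smallest adjusted p on a probe that is not their brightest; their brightest probes differed by 0.63 ± 0.44 and 0.15 ± 0.10. The lowest p among genes lower in Tx belonged to Cd3d, followed by Gadd45g, Gse1 at -0.74 ± 0.11 on 1 of its 2 probes, Asic4 and Fscn2 at -0.79 ± 0.12 (adjusted p = 0.0957). Asic4 was well above background on 3 of 4 nonTx arrays and on 0 of 4 Tx arrays, so no fold is given, and with dim values set to a floor its difference was 0.05 (adjusted p = 0.921), without the lower direction. Without Tx replicate 2, 126 probes passed as higher and 62 as lower, 94 and 42 when counted as genes, among them Cd3d (-1.21), Jchain (1.15) and Vav2 (1.32). The counts were 3 higher without Tx replicate 3, 2 higher and 1 lower without Tx replicate 4, 1 lower without Tx replicate 1, and 1 higher without nonTx replicate 2 or 3. The unadjusted count rose to 6315 without Tx replicate 1.

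Some genes best known from other organs were high in single arrays. In Tx replicate 4 the saliva protein gene Bpifa2 reached a signal of 79620, against at most 163.5 on the other 7 arrays, and 13 of 33 salivary gland genes lay at least 8.02-fold above every other array. On each of the other 7 arrays, 0 of the 33 lay that far above the rest. In the authors' deposited table Bpifa2 has the largest log2 difference, 3.07, and of the other salivary gland genes Dcpp2, Dcpp1, Dnase1, Dcpp3 and Smr3a stand at 2.88, 2.85, 2.67, 2.56 and 2.23. In nonTx replicate 3 the pancreatic enzyme genes Try4, Try5, Prss3, Cpa1 and Cpb1 gave signals of 209.4, 201.4, 159.1, 163.3 and 94.41 and were well above background on that array only. All 8 arrays lay on 1 slide, with the nonTx arrays on one side and the Tx arrays on the other, so position on the slide and group cannot be told apart for any value given here.

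**Figure D4:**
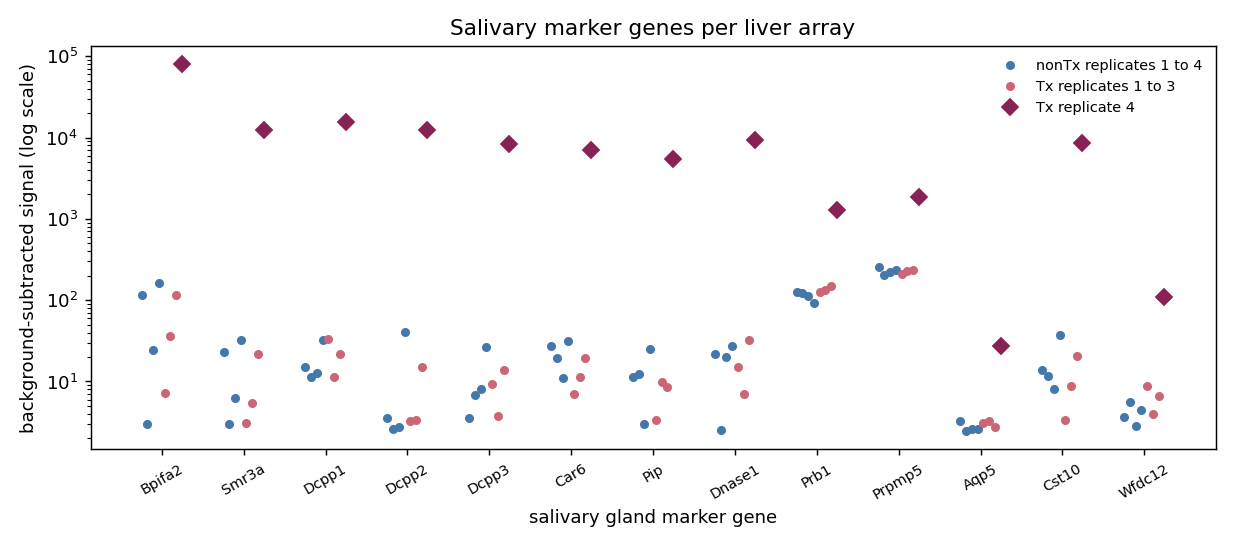
Each point is the background-subtracted signal of 1 array on a log axis, for the 13 salivary gland genes that lay 8-fold or more above every other array in Tx replicate 4, drawn as diamonds; circles are the other 7 arrays. Bpifa2 reached 79620 in Tx replicate 4 and at most 163.5 elsewhere, and Aqp5, the dimmest, 27.27 against at most 3.299.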

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

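Gaps between 1 array and the other 3 of its group were searched for among the named genes and the gene lists, a planned search apart from the immunoglobulin list, which was added after the data were seen; chance flags about 1 in 20 groups, so of 264 groups 13.2 were expected by chance and 19 were found. Values are log2 deviations of the array from the mean of the other 3. Interferon gamma response genes stood apart in Tx replicate 2, where the list lay 1.39 above the other Tx arrays, Cd274 (the checkpoint ligand PD-L1) 2.35, the interferon-induced inhibitor Socs1 1.09 and Parp9 0.45. The interferon-induced gene Trim30a lay 0.40 higher in nonTx replicate 4. The immunoglobulin constant regions lay 0.30 higher in nonTx replicate 1 than in the other nonTx arrays.

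Stress and hormone targets stood apart in other arrays. Gadd45g lay 1.24 higher in Tx replicate 1, and the glucocorticoid target Fkbp5 0.68 higher in Tx replicate 1 and 0.46 higher in nonTx replicate 2. Among liver and cell maintenance genes, Cyp2c54 differed by -0.31 in nonTx replicate 3, the chaperone Calr by -0.49 in Tx replicate 2, Ccnd1 by -0.27 in nonTx replicate 1 and Uqcrfs1 by -0.18 in nonTx replicate 4, and the bile acid list lay 0.06 higher in nonTx replicate 1. Markers of other cells and tissues were the neutrophil gene Csf3r, at -0.69 in Tx replicate 3, the pancreatic Ctrb1 and the adipocyte gene Fabp4, 0.66 and 0.38 higher in nonTx replicate 3, and the muscle gene Actc1, 0.59 higher in nonTx replicate 2 and at -0.22 in Tx replicate 1. None of these flags was weighed further.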

How the results depend on the processing

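The T cell list kept its call in 22 of 24 alternatives. The immunoglobulin constant regions, a list made after the data were seen, kept theirs in 22 of 23. T cells passed 0.05 neither with an estimated correlation (adjusted p = 0.607) nor with fry (0.0666), and the constant regions failed with an estimated correlation (0.422). Without 1 array the T cell list ran from 2.49e-10 to 3.6e-06 and the constant regions from 9.78e-08 to 0.000746. Probes past the threshold, 0 higher and 0 lower by limma (4085 at an unadjusted p under 0.05; a plain equal-variance test also gave 0), became 2 higher with normexp, 5 higher and 1 lower with median scaling, 1 lower with no variance trend, 4 higher and 1 lower with robust variance, 4 higher and 3 lower with array weights, and 16 higher and 10 lower at an adjusted p under 0.1. Genes lower, 0 as well, became 1 with median scaling, 1 with no trend, 1 with robust variance, 3 with array weights and 7 at an adjusted p under 0.1, where 6 were higher. Without 1 array, probes higher ran from 0 to 126, probes lower from 0 to 62, genes higher from 0 to 94 and genes lower from 0 to 42, each highest without Tx replicate 2. The unadjusted count ran from 2909 to 6315, highest without Tx replicate 1. Lists higher, 11, became 6 with normexp, 5 with quantile normalization, 6 with no filter on dim probes, 0 with an estimated correlation, 0 with fry and 4 with its mixed test; lists lower, 4, became 0, 0 and 1 with the last 3. Without 1 array lists higher ran from 8 to 13 and lists lower from 2 (without nonTx replicate 4 or Tx replicate 4) to 5 (without nonTx replicate 1 or Tx replicate 2). Oxidative phosphorylation changed direction with quantile normalization (0.893) and T cell receptor chains with no filter on dim probes (0.942). Of 88 named genes, 0 changed direction past the threshold, which says little about stability since 0 genes passed it in the main setting. Without passing it, 4 named genes changed direction in an alternative. Lists did so in 83 combinations of list and alternative. Median scaling moved the share of probes higher in Tx from 52.6% to 68.1%, normexp to 62%, quantile normalization to 49.3% and scaling to bright probes to 42.4%. With a replicate block 1 probe was higher, the adipocyte call ended (adjusted p = 0.0608) and cell cycle (0.000124), PPARa (0.0388) and female-biased genes (0.0388) were called higher; residuals of arrays with the same number correlated at 0.046, 0.081, 0.099 and -0.01, so the numbers share no pairing, and replicates 2 and 3 alone correlated best with their own number. Except for the list tests, whose correlation setting is their construction, the cause was not tested. Normexp on the mean signal (no such column) and a slide block (1 slide) were not run. Dim probes limit what can be ranked: between 51.1% and 57.12% of probes were well above background per array.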

Other observations

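The tests by other splits were planned for the lists fixed beforehand. All tests of the immunoglobulin and T cell receptor chains, the lists matched on signal level, and the tests on other white blood cells, B cells, slide position, salivary genes and second probes were chosen after the group differences were seen. Clock genes stood apart in Tx replicate 1, where Dbp had a signal of 26920 (3389 to 9868 on the other arrays), Per2 of 1929 (419.7 to 912.3) and Usp2 of 1435, while Arntl, which peaks at the opposite phase, was lowest there at 106.7. The proliferation genes Mki67 and Top2a were highest in nonTx replicate 3 and Tx replicate 3, Mki67 at 302.5 and 284.6 (71.63 to 181.3 elsewhere) and Top2a at 168.2 and 147.1 (23.21 to 80.57 elsewhere). Cdk1 deviated from its mean over the arrays by only -0.10 and 0.33 there, on the log2 scale. The interferon-induced GTPase genes Tgtp2 and Igtp reached 81890 and 57070 in Tx replicate 2, against at most 4873 and 10710 in the other Tx arrays. They were also high in nonTx replicates 2, 3 and 4 (Tgtp2 at 36090, 42020 and 71340, Igtp at 34900, 40400 and 53060) and low in nonTx replicate 1 (5242 and 8658). The mesothelial genes Msln and Wt1 were lowest in Tx replicate 2, at 5.511 and 9.343, against at least 60.13 and 27.06 elsewhere. Tx replicate 3 had 584 probes at least 4-fold below the median of the others.

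Other ways to split the 8 arrays 4 against 4, 35 in all with the real split included, were run for part of the results. These were the 15 called lists, the immunoglobulin constant regions, the T cell receptor chains and the counts of probes and lists. Single genes, lists not called and the 48 immunoglobulin chains together were not tested in this way. The real split ranked first for ribosomal proteins (1 split with a camera p as small, the real one at 9.85e-08, next 9.82e-07). It also ranked first for pericentral genes (1 split, 0.000198, next 0.00223) and for the 4085 probes at an unadjusted p under 0.05 (1 split, next 3713). First of 35 is the smallest share that this test can reach, and it was run on many results without adjustment. A first rank therefore does not exclude chance. Chance was also not excluded for T cells (2 splits, 1.1e-09 against 1.85e-11), T cell receptor chains (2 splits, 2.85e-05 against 2.62e-06), immunoglobulin constant regions (2 splits, 1.81e-07 against 7.47e-08) or adipocytes (2 splits, 0.0119 against 0.00503). It was not excluded for oxidative phosphorylation (4 splits, 5.8e-06 against 2.31e-08), male-biased genes (4 splits, 5.92e-05 against 4.83e-09), xenobiotic metabolism (6 splits, 0.000106 against 3.7e-08), heat shock (7 splits, 0.00588 against 1.28e-06) or NK cells (8 splits, 0.000113 against 1.91e-11). The same held for complement (10 splits, 0.0165 against 3.35e-06), cholesterol synthesis (13 splits, 1.73e-05 against 3.29e-21), MHC class II (13 splits, 0.00405 against 7.06e-15), periportal genes (14 splits, 0.0185 against 1.78e-08) and fatty acid synthesis (15 splits, 0.00532 against 2.74e-09). For interferon gamma genes 20 splits gave a camera p as small (0.00683 against 7.52e-34) and 11 splits called as many lists (15, highest other 20). The count of probes at an adjusted p under 0.05 decides nothing, since the real split gave 0, which all 35 reach (highest other 47). The split with 47 set nonTx replicate 1 and Tx replicates 1, 3 and 4 against the rest, which points to a structure of the samples across the groups.

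Lower T cell transcripts in Tx were argued against as a shift that depends on signal level, since 0 of 10000 random lists matched on level had a median as low as T cells (-0.47), though 253 lay as low as the T cell receptor chains (-0.27). Likewise 0 lay as high as the immunoglobulin constant regions (0.95). That list was made after its values were seen, so this comparison cannot decide the question for immunoglobulins. Against a general loss of white blood cell RNA, the pooled median of B cell, Kupffer cell and neutrophil genes was 0.04 (95% interval -0.001 to 0.087, 60 genes). The T cell interval ran from -0.63 to -0.337. Against more B cells, the B cell median was 0.05 (-0.022 to 0.227). All intervals here came from resampling the genes of a list, not the arrays. They do not measure the spread between samples, so the values describe these arrays and exclude neither explanation. The NK list (-0.32) and the MHC class II and dendritic cell list (-0.40) were also called lower, so a loss shared by these cells stays open, although the pooled median with both added was -0.003 (-0.048 to 0.04, 90 genes). Position on the slide cannot be told apart from group, since 0 sides of the slide held both groups. Fewer T cells and more antibody-secreting cells in livers of thymectomised mice may underlie the pattern, which stays open beside slide position and chance, and was not tested. The plasma cell list fixed beforehand was not called by camera (median 0.13, adjusted p = 0.428).

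The salivary gland transcripts of Tx replicate 4 were the second pattern. Salivary gland RNA in this sample is a candidate explanation: of 33 marker genes listed before the test 13 were raised, and of the 27 outside the authors' highest probes 7 were (25.9%), against 0.0302 expected from 30 of 26833 other genes (Fisher's exact test, one-sided, p = 4.48e-15). Among the raised markers were Bpifa2 at 79620, Dcpp1 at 15320, Dcpp2 at 12250 and Smr3a at 12220. Amy1, at 33190, lay 2.21-fold above the highest other array after scaling. Smr2 at 4.305, Prol1 at 3.465 and Muc19 at 34.39 were not raised, and 13 of the 33 were well above background on at least 6 of the other 7 arrays, so the liver arrays read them too. Defective spots were argued against, since 4 raised genes had a second raised probe, though Pip and Aqp5 each had only 1 of 2 probes raised. Expression of these genes by the liver of that mouse stays open, and no biological explanation was tested.

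The small rise of ribosomal protein and oxidative phosphorylation genes was the third pattern. A shift that depends on signal level may account for it: 752 of 10000 matched lists had a median as high as the ribosomal list and 6255 as high as oxidative phosphorylation. It stays open for heat shock, adipocyte, complement and periportal genes too, with 457, 433, 2475 and 1485 matched lists as high. The effect of thymectomy on these genes stays open, as untested.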
